A study of Mus musculus with 18 samples.

How the data were processed

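Gene expression was measured in the whole brain of mouse pups at postnatal day 8. Per the labels, the pups were wild-type (+/+), heterozygous (+/-) or homozygous (-/-, called Mt-KO) for a metallothionein knockout kept on the C57BL/6J background after at least 7 backcross generations. Lead acetate (50 mg/kg) or saline was injected 2 times a day, 4 h apart, on postnatal days 7 and 8, and brains were taken 6 h after the last injection. RNA of 5 pups was pooled per genotype and treatment, and each pool was hybridised to 1 Affymetrix mouse expression array, which gave 6 arrays. The labels describe the pups as male and female. The labelling kit they name belongs to whole-transcript arrays, whereas the probe set identifiers are those of a 3' expression array, and this difference was left open.

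The 18 deposited columns are the same 6 arrays summarised by 3 algorithms, so they were never counted as replicates. Per the submitters' processing notes, the tools were Partek, RMA, GCRMA and PLIER, with versions and settings not given in the sources used here. The deposited RMA and GC-RMA values are on a log2 scale. The deposited PLIER values are intensities on a linear scale and were used as log2(value + 16). RMA was the main setting. The deposited RMA columns are not forced to one distribution. The median lead minus saline difference over the genes tested was -0.18 in the wild-type pair, 0.15 in the heterozygous pair and 0.09 in the Mt-KO pair (log2), so the differences of single pairs are given relative to the median gene of that pair. Fitted coefficients are given as estimated from the deposited values, and their medians over genes were 0.02 for lead, -0.03 for Mt-KO and 0.00 for the heterozygote. The number of arrays limits the precision.

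The value table holds 45101 probe sets. The platform annotation gave 1 gene symbol for 34958 of them, several for 932 and none for 9211, and probe sets with several or none were left out. Of those with 1 symbol, 34754 were found by gene identifier in the GRCm38.p6 gene table, with no symbol differing. Each of the 18194 genes was represented by its brightest probe set, and the upper 60% by mean RMA value, 10916 genes, were tested.

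Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg threshold 0.05). An additive fit of genotype and treatment gave the lead coefficient (3 lead arrays against 3 saline arrays, with genotype as a block) and the coefficients of Mt-KO and heterozygous against wild-type (2 arrays against 2, with treatment as a block). The genotypes stand in as replicates of the lead effect, and 2 residual degrees of freedom remain. A second fit tested the interaction of treatment with the number of intact alleles, taken as linear, also with 2. In the RMA and PLIER fits limma estimated an infinite prior, so each gene received the spread typical of its brightness and its own spread between arrays had no weight. The prior had 4.94 degrees of freedom with GC-RMA and 4.75 after quantile normalization (6.24 in the interaction fit). No combination of genotype and treatment was replicated, so spread between pools was not estimated apart from departures from the fitted model. The p-values rest on what each fit left over, averaged over genes of similar brightness in the RMA and PLIER fits.

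Before the data were examined, 41 gene lists were fixed (cell types, brain regions, stress pathways and synaptic groups), as were the genes to be named. Older symbols in the lists were replaced by current ones through the synonyms of the gene table, and genes measured only by probe sets with several symbols were left out of the lists. These are the 12 largest rises and falls with lead that passed and went the same way in all 3 genotypes, 10 each way for Mt-KO, 5 each way for the heterozygote and the interaction, and up to 4 members per list by size of t. Places left open were filled with genes that did not pass, ranked by their smallest single difference. Metallothioneins, Xist and Y-linked genes were always named. Lists with at least 4 genes tested (37 of them) entered limma's camera with a preset correlation of 0.01. At that setting camera compares genes of a list with the other genes, so its p-values take genes rather than pools as units. Camera with an estimated correlation, which uses the 2 residual degrees of freedom of the fit, and fry were run as alternatives. Medians were set against 10000 random lists matched on mean level. For Mt-KO, the 89 tested genes within 10 Mb of Mt1 in the gene table formed 1 more list.

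The alternatives were GC-RMA, PLIER, quantile normalization of the RMA values, no brightness filter, the upper 40% of genes, the mean over a gene's probe sets, eBayes without trend, no genotype block, a linear allele term, a threshold of 0.10, a lower and a higher fold limit, and leaving out each pair or array. Centring each array on its median was added after seeing the data. So were fits that hold the spread of the deposited values on rescaled values, and a fit of the deposited values with each gene's own spread weighted as after quantile normalization.

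The fits were tested on simulated data for 10916 genes with the fitted spread and 200 genes changed. For lead against saline, 54.5% of genes changed by 0.5 (log2) and 97.5% of those changed by 1 were recovered. For Mt-KO against wild-type the shares were 23.0% and 94.0%, and for the interaction 98.5% at 1. A list of 20 genes shifted by 0.1 was called in 30.0% of 20 simulations, and one shifted by 0.2 in 100%. These simulations hold no brightness shift between arrays and no gene with a spread of its own. Python 3.11.15 with matplotlib 3.10.9 drew the figures.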

Results

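The arrays covered 3 genotypes and 2 treatments, with 1 pool of 5 pups in each combination. The design asks how acute lead exposure during synapse formation changes brain expression, and whether that depends on metallothioneins, small cysteine-rich proteins that bind zinc, copper and toxic metals. No combination was replicated. The median RMA value over all probe sets lay between 9.10 and 9.15 on every array, whereas the median of the genes tested ranged from 10.87 in wild-type lead to 11.05 in wild-type saline. Correlations between arrays across genes ranged from 0.982 to 0.993. The Gapdh 3' probe set exceeded the 5' probe set by 1.19 (log2) in the wild-type saline pool and by 0.54 to 0.82 in the other 5 pools.

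Mt1 and Mt2, the widely expressed metallothioneins, followed the genotype. The brightest Mt1 probe set measured 13.17 and 13.30 in the wild-type saline and lead pools, 12.45 and 12.87 in the heterozygous pools, and 11.68 and 11.71 in the Mt-KO pools. Mt1 was 2.91-fold lower in Mt-KO than in wild-type brain (log2 -1.54, SE 0.22, limma adjusted p = 6.0e-09), and Mt2 was 1.75-fold lower (log2 -0.81, SE 0.21, limma adjusted p = 0.0213). The heterozygous differences, -0.57 for Mt1 and -0.50 for Mt2, did not pass (limma adjusted p = 1 for both). A dimmer Mt1 probe set differed by -0.12 between Mt-KO and wild-type. With GC-RMA neither passed (limma adjusted p = 0.0848 for Mt1 and 0.178 for Mt2), and after quantile normalization Mt1 passed (0.0451) and Mt2 did not (0.232). The sources used here do not say which part of either gene was altered, so remaining signal does not contradict the labels.

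Lead did not raise the metallothioneins past the threshold. The lead coefficient was 0.20 (SE 0.18) for Mt1, 0.11 (SE 0.17) for Mt2 and -0.08 (SE 0.22) for the brain-enriched Mt3, each with a limma adjusted p of 1. Mt4 lay at 6.19 to 6.46 on all arrays and was too dim to be tested.

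**Figure D1:**
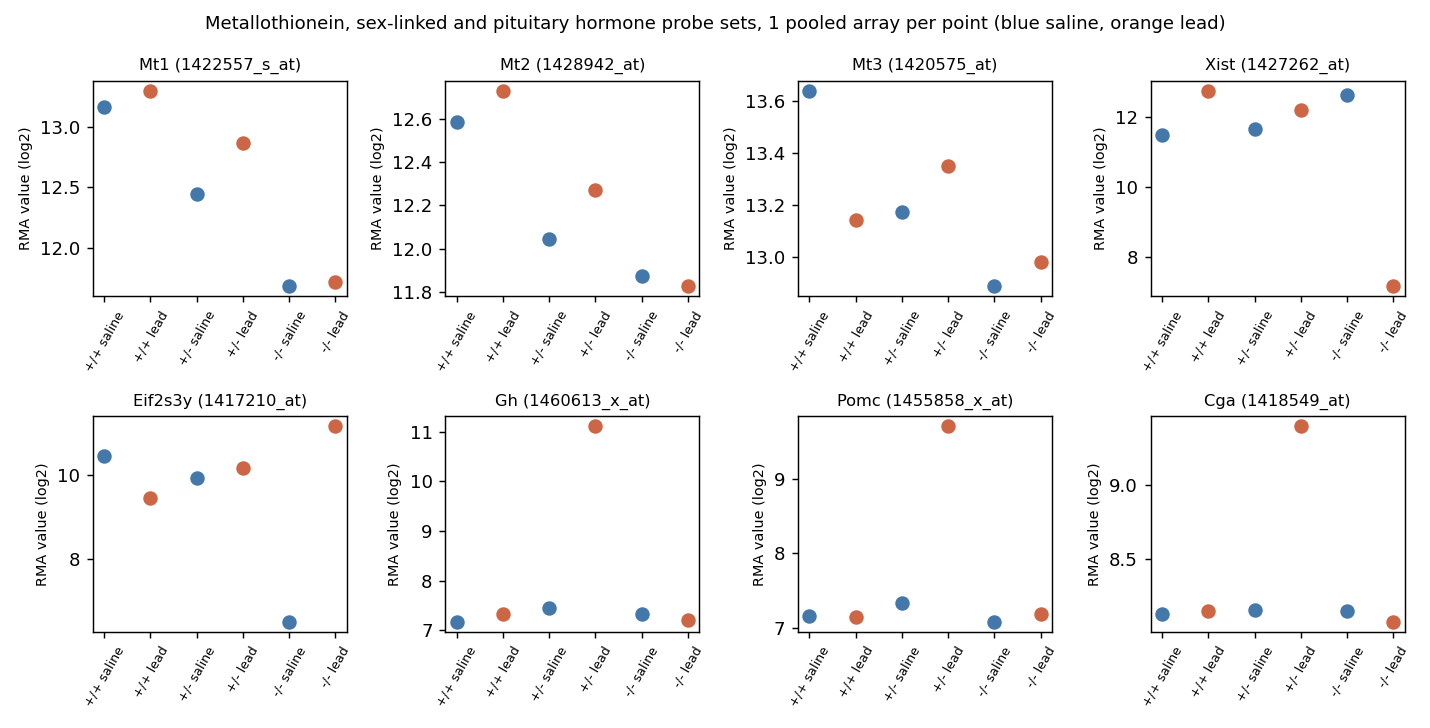
RMA values (log2, vertical axes) of 8 probe sets on the 6 arrays, with 1 point per pool, blue for saline and orange for lead. Mt1 falls from 13.30 in wild-type lead to 11.68 in Mt-KO saline, Xist is 7.14 in the Mt-KO lead pool alone, and Gh, Pomc and Cga stand high in the heterozygous lead pool.

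The pools differed in sex-linked and pituitary transcripts. Xist, the RNA that coats the inactive X chromosome of females, measured 12.63 in the Mt-KO saline pool and 7.14 in the Mt-KO lead pool, while the Y-linked gene Eif2s3y measured 6.50 and 11.16. Kdm5d and Uty, also Y-linked, were 6.07 and 6.23 in the Mt-KO saline pool and 9.13 and 9.09 in the Mt-KO lead pool. The other 4 pools held both kinds of transcript, with Xist at 11.50 to 12.76 and Eif2s3y at 9.45 to 10.45. Within the wild-type pair, lead minus saline was 1.26 for Xist, -1.01 for Eif2s3y, -0.93 for Kdm5d and -1.25 for Uty, opposite to the Mt-KO pair. In the heterozygous pair it was 0.53 for Xist and 0.22 for Eif2s3y. The lead comparison in Mt-KO brain, and by smaller amounts that in wild-type brain, is thus also a comparison of pools with different sex-linked expression. Growth hormone (Gh) measured 11.11 in the heterozygous lead pool and 7.17 to 7.45 in the others, Pomc 9.70 against 7.08 to 7.33, and Cga, the shared subunit of pituitary glycoprotein hormones, 9.40 against 8.07 to 8.15. For Xist, Kdm5d, Uty, Gh and Pomc these values come from probe sets chosen after their values were seen. The brightest probe sets, which entered the fits, moved less, with Xist at 12.75 and 10.23 in the Mt-KO saline and lead pools and Gh at 11.48 in the heterozygous lead pool against 9.29 to 9.83.

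Among the genes that passed and went the same way in all 3 pairs, the largest rises with lead were those of Insm1 and Nhlh2, transcription factors expressed in developing neurons. They rose by 0.68 (SE 0.13) and 0.67 (SE 0.12) on the log2 scale, En2, a patterning factor of midbrain and cerebellum, by 0.55 (SE 0.12), and Pax6, expressed in cerebellar granule cell precursors, by 0.54 (SE 0.12). Hmgb2, St18 and Vwf rose by 0.62, 0.57 and 0.47. Hoxa5, a gene of hindbrain and spinal cord, fell by 0.60 (SE 0.13), with differences of 0.08, -1.07 and -0.85 from the median gene in the wild-type, heterozygous and Mt-KO pairs. These 8 went the same way in all 3 pairs as deposited, and limma adjusted p ranged from 3.4e-05 for Nhlh2 to 0.0206 for Vwf. All 8 passed without the wild-type pair, a fit in which 2632 of all 10916 genes passed (2461 higher, 171 lower). None of the 8 passed without the heterozygous pair (limma adjusted p from 0.303 for Nhlh2) or without the Mt-KO pair (1 for all).

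In all, 13 of 10916 genes passed, 9 higher and 4 lower. The other 5 were Eif2s3y (1.29), Gh (0.85) and Xist (-0.79), which differ in single pools as given above, and Stap2 (-0.58) and Cdhr1 (-0.54), named after their values were seen. The largest rises by rule that did not pass were Car8 (0.50), Lhx1 (0.47), Neurod1 (0.46), Nhlh1 (0.41) and Zfp521 (0.40). On the lower side Gnb1 (-0.57), Minar2 (-0.50), Mrps21 (-0.42), Sod1 (-0.39), Eef1akmt1 (-0.36), Inpp4a (-0.36), Rassf1 (-0.32), Tmem181a (-0.31), Adarb1 (-0.24), Arglu1 (-0.23) and Erich3 (-0.21) did not pass either. No gene shifted at least 1.5-fold in all 3 genotypes, as deposited or relative to the median gene. Relative to the median gene, 2 genes did so with the sign of the wild-type pair turned and 0 with that of either other pair turned, whereas as deposited the numbers were 0 for wild-type, 1 for heterozygous and 0 for Mt-KO. At the lower fold limit set beforehand, 6 genes went the same way in all 3 pairs relative to the median gene (Hmgb2, Insm1, Nhlh2, Pax6 and St18 up, Gnb1 down), against 47 with the wild-type pair turned, 1 with the heterozygous pair turned and 0 with the Mt-KO pair turned.

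The lead calls depended on limma's shared spread. With GC-RMA, after quantile normalization and without the trend limma called 0 genes, with 294, 552 and 114 at an unadjusted p under 0.05 against 167 in the RMA fit, and PLIER called 13, with 2 higher and 11 lower, of which 3 were shared. After quantile normalization the coefficients stayed similar (Insm1 0.65, Nhlh2 0.64, Hoxa5 -0.63), whereas over the mean of the probe sets Pax6 was 0.18, Hoxa5 -0.28 and St18 0.29. In fits added after seeing the data, all 13 genes passed on quantile-normalized values with the spread of the deposited values held, and 0 (81 at an unadjusted p under 0.05) on deposited values with each gene's own spread weighted as after quantile normalization.

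Cerebellar genes were higher with lead as a group. Over the 14 tested genes of the cerebellum list the median shift was 0.28 above the median gene, and 13 of 14 lay above it. Camera called the list (limma adjusted p = 5.9e-21, adjusted p = 0.337 with an estimated correlation). The estimated correlation was -0.07, below the preset 0.01, so correlation between genes does not account for the larger p-value. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit. At the preset correlation the number of genes sets them, so the small p-value does not measure spread between pools. En2 rose over all genes, and 6 genes rose when adjusted over the list alone. The median difference was 0.56 in the wild-type pair, 0.23 in the heterozygous pair and 0.21 in the Mt-KO pair. The Purkinje cell gene Pcp2 differed by 1.18 in the wild-type pair and by 0.05 in each of the others, Car8 by 0.80, 0.29 and 0.35, and the glutamate transporter gene Slc1a6 by 0.83, -0.13 and 0.22.

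**Figure D2:**
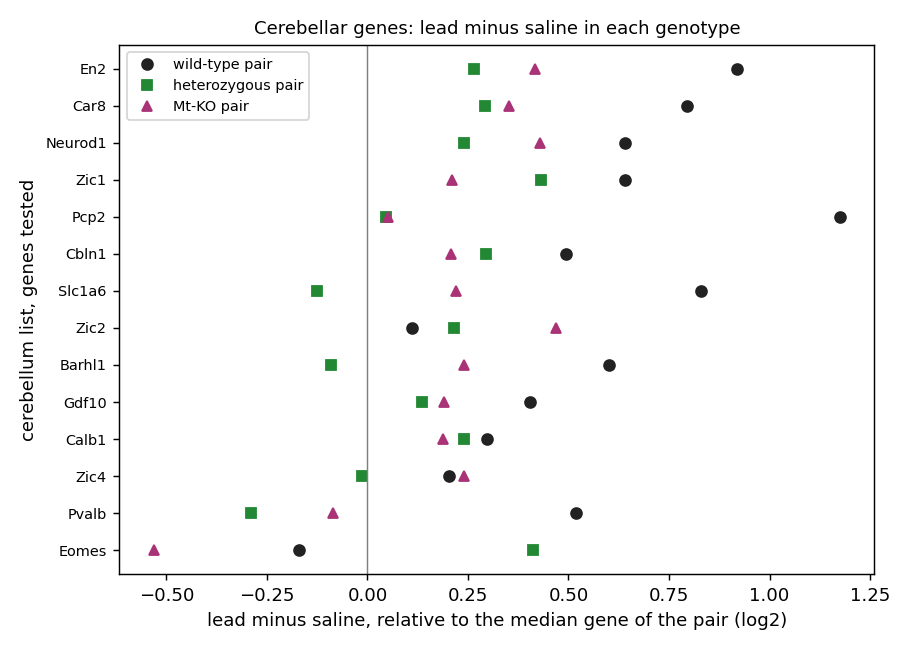
Lead minus saline difference (log2, horizontal axis) of the 14 tested cerebellar genes (vertical axis), relative to the median gene of each pair, with 1 symbol per genotype pair. Most symbols lie right of 0, and the wild-type pair reaches 1.18 for Pcp2.

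Glial and proliferation lists shifted up by less. All 18 astrocyte genes, led by Gjb6 (0.29) and Gfap (0.28), lay above the median gene (median 0.14, limma adjusted p = 0.000101), with similar medians of 0.14, 0.15 and 0.14 in the wild-type, heterozygous and Mt-KO pairs. The microglia list, led by C1qa (0.36), Ctss (0.36) and C1qb (0.32), had a median shift of 0.09 (limma adjusted p = 1.5e-05), the cell division list, led by Ccna2 (0.32) and Mki67 (0.27), one of 0.10 (4.8e-05), and the myelin list, led by Cldn11 (0.24) and Ugt8a (0.21), one of 0.11 (0.00463). In the wild-type, heterozygous and Mt-KO pairs the medians were 0.25, 0.11 and 0.01 for microglia, 0.24, -0.02 and 0.11 for cell division, and 0.39, -0.16 and 0.05 for myelin. Pericyte genes, led by Acta2 (-0.25), shifted down (median -0.10, limma adjusted p = 0.0227), as did a list of 4 muscle, bone and skin genes led by Krt10 (-0.20; median -0.13, 0.0381). The wild-type pair went the other way in both, with medians of 0.11, -0.20 and -0.19 for pericytes and 0.07, -0.14 and -0.19 for muscle, bone and skin. No member of these 6 lists passed over all genes. Adjusted over the list alone, 3 microglia genes passed and 0 genes of the other 5 lists did. The adjusted p with an estimated correlation was 0.991 for astrocytes and microglia and 0.830 for the other 4 lists, and fry called 0 lists. Heat shock, NRF2, metal transport, heme and ATF4 lists were not called (limma adjusted p from 0.792 to 0.980). The same held for immediate early genes (0.678), glutamate receptors (0.934) and presynaptic genes (0.934).

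Single genes beyond the metallothioneins differed between Mt-KO and wild-type brains. Gabra2, a GABA-A receptor subunit, was 2.61-fold higher (log2 1.38, SE 0.16, limma adjusted p = 6.9e-15), and 3 of its 5 probe sets differed by 1.16 to 1.40, with 0.33 and 0.12 for the dimmer ones. Laptm5 (1.47), Tspyl1 (1.30), Tmem267 (2.37-fold), the RNA-binding protein gene Rbm45 (1.23), Samhd1 (1.20), Srr (1.14), Exoc8 (0.99), Nrip2 (0.97) and Rpl27a (0.97) were also higher. Several of these sizes depended on the summary, with Rbm45 at 0.39 with GC-RMA and 0.22 with PLIER, Samhd1 at 0.53 with GC-RMA, and Laptm5 at 0.28, Srr at 0.26, Nrip2 at 0.32, Samhd1 at 0.41, Exoc8 at 0.44 and Rpl27a at 0.53 over the mean of the probe sets. Gm6958 was lower by the most (-2.09, limma adjusted p = 1.5e-41), followed after Mt1 by Eif2s3y (-1.12), Megf11 (-0.94), the nuclear RNA Malat1 (-0.90), Pcdh17 (-0.76), Srek1 (-0.73), 5730455P16Rik (-0.71) and Zic2 (-0.65). Over the mean of the probe sets Megf11, Malat1 and 5730455P16Rik were each -0.39 and Srek1 -0.18, none passing. The Eif2s3y difference rests on the Mt-KO saline pool and was 1.41 without it. Laptm5 measured 10.62 and 12.45 in wild-type saline and lead and 13.13 and 12.87 in Mt-KO saline and lead. Relative to the median gene, Mt-KO minus wild-type was 1.87 between the saline pools and 0.12 between the lead pools for Nrip2. It was 1.85 and 0.48 for Srr, 1.88 and 0.58 for Samhd1, -1.64 and -0.11 for Malat1 and -1.23 and -0.24 for Pcdh17. These genes and Laptm5 (2.66 and 0.33) thus differed mainly between the saline pools. Gabra2 (1.055 and 1.76) and Tmem267 (0.74 and 1.81) differed more between the lead pools, and Rbm45 and Srek1 alike in both. For the genes that differed mainly between the saline pools, heterozygous saline departed from wild-type saline in the same direction. Relative to the median gene these differences were 2.51 for Laptm5, 1.55 for Nrip2, 1.36 for Srr, 1.23 for Samhd1, -1.14 for Malat1 and -0.57 for Pcdh17. Both comparisons rest on the single wild-type saline array, which had the largest Gapdh 3' excess (1.19).

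In all, 47 genes passed for Mt-KO, 34 higher and 13 lower. Single arrays moved this number, with 2429 genes (2203 higher) without wild-type saline, 4380 (414 higher) without wild-type lead, and 8 and 11 without the Mt-KO saline and lead arrays. After centring the arrays 7 passed, with 3 higher and 4 lower, of which 6 were among the 47, quantile normalization left Mt1 alone (994 genes at an unadjusted p under 0.05 against 382), GC-RMA left 0 (592 genes) and PLIER called 68, of which 25 were shared. With the spread of the deposited values held, 45 of the 47 passed after quantile normalization.

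Among gene lists in Mt-KO brain, cell division genes were higher, with 16 of 16 above the median gene (led by Ccnb2, 0.30; median 0.21, limma adjusted p = 4.7e-05), as were cerebellar genes (median 0.21, 0.0470; 0.36 between the saline pools and 0.03 between the lead pools) and cholesterol synthesis genes led by Fdps (0.45) and Sc5d (0.34; median 0.07, 0.0470). Calcium channel and pump genes were lower, led by Cacna1b (-0.45; median -0.11, limma adjusted p = 0.0370), as were presynaptic genes, led by Slc17a7 (-0.38; median -0.15, 0.0470), and respiratory chain genes, led by Cox5a (-0.55; median -0.14, 0.0470; -0.27 between the saline pools and -0.02 between the lead pools), whose direction turned after quantile normalization. Against random lists matched on level the medians lay at percentile 7.49 for calcium, 37.1 for presynaptic and 90.01 for respiratory chain genes, the last of which is higher than most lists of its brightness, and after quantile normalization calcium (0.0527) and presynaptic genes (0.541) were not called. Those of the other 4 lists lay at 0.06 for glucocorticoid, 98.8 for cholesterol and 100 for cell division and cerebellum. The glucocorticoid response list (median -0.15, limma adjusted p = 4.7e-05) contains Mt1 and Mt2, and without them, a test added after seeing the data, it was not called (median -0.09, 0.107). Over all genes 2 members of the glucocorticoid list were lower, Mt1 and Mt2, and 1 of the cerebellum list, Zic2. Adjusted over the list alone the numbers were again 2 and 1, and the other 5 lists had 0 either way. Each call was lost with an estimated correlation (adjusted p = 0.990 for all 7) and with fry. The 89 genes near Mt1 had a median shift of 0.00 and were not called (0.833).

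Several genes called in heterozygous brains were also called in Mt-KO brains. Gabra2 (1.02, SE 0.16, limma adjusted p = 4.5e-07), Tspyl1 (0.78) and Exoc8 (0.77) were higher and Gm6958 (-1.11), Megf11 (-0.68) and Malat1 (-0.73) lower, while Pomc (0.87) and Gh (0.82) were higher mainly in the heterozygous lead pool and Prmt1 (-0.83) and Galc (-0.62) were lower. Relative to the median gene, heterozygous minus wild-type was -1.17 between the saline pools and -0.09 between the lead pools for Galc. Exoc8 (1.27 and 0.25), Tspyl1 (1.249 and 0.305) and Malat1 (-1.14 and -0.33) also differed mainly between the saline pools. Gabra2 (1.15 and 0.88), Prmt1 (-1.10 and -0.56) and Megf11 (-0.92 and -0.45) differed in both, and Gm6958 (-0.82 and -1.42) more between the lead pools. Over the mean of the probe sets no gene passed, with Gabra2 at 0.56, Tspyl1 at 0.49, Exoc8 at 0.43, Malat1 at -0.40, Megf11 at -0.37 and Galc at -0.15. Limma called 13 genes on the brightest probe sets, 8 higher and 5 lower. Of these, 5 higher and 3 lower were also called in Mt-KO, from the same wild-type arrays. Across genes the coefficients of both genotypes correlated at 0.682, against 0.501 in simulations of unchanged groups that share the wild-type arrays, with a covariance of 0.0127 against 0.0176. The wild-type arrays are too few to be divided between both comparisons, so the overlap was not tested. No heterozygous call was made after quantile normalization (306 genes at an unadjusted p under 0.05 against 131) or with GC-RMA (161), and all 13 passed after quantile normalization with the spread held.

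Lead responses of the wild-type pair correlated negatively with those of the other pairs. Across genes, which are not independent replicates, the lead minus saline difference of the wild-type pair correlated at -0.31 with that of the heterozygous pair and at -0.31 with that of the Mt-KO pair, whereas the latter correlated with each other at 0.49. The signs were equal in all 3 pairs for 12.4% of genes as deposited and for 22.4% relative to the median gene, and for 25.2% after quantile normalization, where chance gives 25%. After quantile normalization the correlations were -0.23, -0.25 and 0.42.

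**Figure D3:**
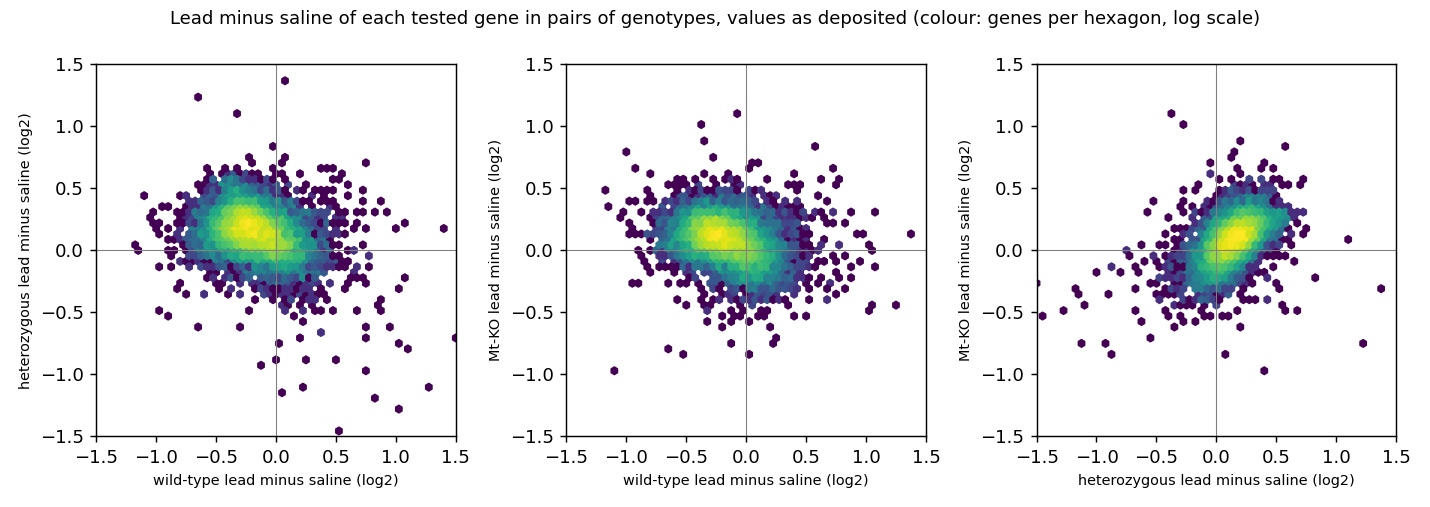
Lead minus saline difference (log2, as deposited) of each gene tested in 1 genotype pair against another, coloured by genes per hexagon on a log scale. The clouds slope down for wild-type against the other genotypes and up for heterozygous against Mt-KO, and 6 genes beyond the axis limits of -1.5 and 1.5 are not drawn.

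A linear slope of the lead response on the number of intact alleles was called for 412 genes, 47 rising and 365 falling. As the allele numbers are evenly spaced, the size of this slope is set by the wild-type and Mt-KO pairs alone. The heterozygous pair enters only the residual spread, so a call does not show a graded response over the 3 genotypes. Xist (1.41 per allele, SE 0.13), Laptm5 (1.04), 1700003E16Rik (0.91), Pik3cd (0.86) and the peptide gene Iapp (0.76) had the largest rising slopes by rule, and Eif2s3y (-2.83, SE 0.11), Malat1 (-0.89), Mapre2 (-0.84), the transcription factor gene Tcf7l2 (-0.78) and Rnpc3 (-0.76) the largest falling ones. The largest limma adjusted p among these 10 was 0.0166, for Pik3cd. In Laptm5, 1700003E16Rik and Pik3cd the heterozygous pair lay below the Mt-KO pair, so these responses did not run in allele order. Relative to the median gene, the wild-type, heterozygous and Mt-KO differences were 2.01, -1.64 and -0.35 for Laptm5. They were 1.86, -1.04 and -0.23 for 1700003E16Rik and 1.46, -1.27 and -0.54 for Pik3cd. The others among these 10 genes ran in allele order. Over the mean of the probe sets Laptm5 (0.16), Pik3cd (0.20) and Mapre2 (-0.24) did not pass, and Iapp (0.26), Malat1 (-0.44), Tcf7l2 (-0.36) and Rnpc3 (-0.50) passed with smaller slopes. With PLIER, Pik3cd (limma adjusted p = 0.138), Iapp (0.0535) and Mapre2 (0.146) did not pass. The Xist and Eif2s3y slopes follow the sex-linked expression of the pools given above. The median slope over all genes was -0.15, and 20 genes passed after centring the arrays, 11 rising and 9 falling, of which 17 were among the 412. Quantile normalization left Mapre2 alone (1766 genes at an unadjusted p under 0.05 against 2194) and GC-RMA 0 (1241). With the spread of the deposited values held, 205 genes passed after quantile normalization, 108 rising and 97 falling, of which 144 were among the 412, whose median size of slope went from 0.41 to 0.33. Camera on the slopes, added after seeing the data, called the cerebellum list (median 0.19 above the median gene, limma adjusted p = 0.0413, adjusted p = 0.958 with an estimated correlation), and the call was lost after quantile normalization (0.0686) and held with GC-RMA (0.00511) and PLIER (0.0116).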

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

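The tests on brightness scale, the splits of centred arrays and the tests on a mislabelled sample and on the fixed cerebellum list were chosen after the result was seen. The tests on RNA quality, sex make-up and the further cerebellar genes, and the splits of the deposited arrays, were set before it.

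A linear slope of the lead response on the number of Mt alleles, set by the wild-type and Mt-KO pairs alone, was called for 412 genes. Named among them were Xist (1.41), Laptm5 (1.04), 1700003E16Rik (0.91), Pik3cd (0.86), Iapp (0.76), Eif2s3y (-2.83), Malat1 (-0.89), Mapre2 (-0.84), Tcf7l2 (-0.78) and Rnpc3 (-0.76), each a slope per Mt allele. Genes named for Mt-KO were also among them, with slopes of -0.48 for Gabra2, 0.39 for Tspyl1, -0.66 for Tmem267, 0.53 for Samhd1, 0.56 for Srr, 0.75 for Nrip2, -0.60 for Gm6958, -0.43 for Megf11 and -0.62 for Pcdh17. Relative to the median gene, Gabra2, Samhd1, Srr, Nrip2 and Gm6958 did not run in allele order, nor did Laptm5, 1700003E16Rik and Pik3cd. In each of them the heterozygous pair lay below both other pairs. The cerebellum list had a median slope of 0.19.

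Quantile normalization left 1 of the 412 genes, but it also changed the weight of each gene's own spread, and slopes of the brightest probe sets stayed large (Xist 1.60, Laptm5 1.21, Eif2s3y -2.76, Rnpc3 -0.71), although over the mean of the probe sets Laptm5 (0.16), Pik3cd (0.20) and Mapre2 (-0.24) were not called. With the spread of the deposited values held, 144 of the 412 were still called, between the bounds set for either answer, so the part of array brightness in these calls stays open. A shift in the overall distribution of the arrays does not by itself account for the opposite responses of the wild-type pair. The higher of its correlations with the other pairs stayed at -0.23 after quantile normalization. That step evens only the distribution, so other effects of brightness were not excluded, and with GC-RMA the correlations were -0.0996 and -0.0898. RNA quality of the wild-type saline pool stays open: the contrast between the wild-type pair and the others correlated at 0.274 between 2 probe sets of a gene over 4106 genes, between the bounds set for either answer, and that pool had the largest Gapdh 3' excess (1.19). A dependence of the lead response on metallothioneins also stays open, as each genotype has 1 pair of pools. Xist and Eif2s3y also moved in opposite directions in the wild-type and Mt-KO pairs that set the slope.

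The Mt-KO saline and lead pools differed in Xist and Y-linked genes. X-linked genes that escape inactivation had a median lead minus saline difference of -0.13 in that pair, with 1 of 8 above 0 and at percentile 0.42 of random lists, which is consistent with a mostly female saline pool and a mostly male lead pool. A pool of another genotype is argued against by Mt1, which lay at least 0.736 lower in both Mt-KO pools than in any other pool by its brightest probe set. The dimmer Mt1 probe set did not separate the genotypes (9.13 in Mt-KO saline, 9.06 in wild-type saline), and Mt2 was 11.87 in Mt-KO saline against 12.05 in heterozygous saline. The Mt1 value does not bear on an exchange of the saline and lead labels within Mt-KO, and no biological explanation was tested.

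For cerebellar genes higher with lead, a shift in the overall distribution of the arrays is argued against. The list was called after quantile normalization (limma adjusted p = 7.1e-12), although on the deposited values neither an estimated correlation (adjusted p = 0.337) nor fry (0.101) called it. A smaller share of cerebellum in the wild-type saline pool alone could account for 10 further cerebellar genes, with a median of 0.21 in the wild-type pair (percentile 99.5) and percentiles of 75.7 and 74.7 in the others. For the fixed list the values argue against it, as the lower percentile of the other pairs was 100 and the call held without the wild-type pair (limma adjusted p = 0.00491, at the preset correlation only). That list was singled out by a fit that includes these same pairs, and percentiles take genes rather than pools as units. The explanation was therefore not excluded. The 2 sets thus point different ways. Differences in dissection across several pools and a lead effect on cerebellar cells both stay open.

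The 6 arrays can be split into 3 and 3 in only 10 ways, so the share with as many calls is never under 0.1. The real split called 13 genes against a highest other count of 3010, with 4 of the 10 splits giving as many. It called 7 lists against a highest other count of 7, with 3 splits giving as many, and 412 genes for the allele slope against 375, with 1 split, the real one, giving as many. The split with 375 genes exchanges only the heterozygous labels, so its slopes equal those of the real split and only the residual spread differs. The rank of the real split therefore does not bear on a dependence on allele number. The split with 3010 genes, like the real one, parts every genotype pair and sets wild-type saline with heterozygous and Mt-KO lead, and it gathers the 3 arrays with the highest medians of the genes tested (11.05, 11.04 and 11.01 against 10.87 to 10.92). This points to a structure of the samples, from which array brightness was not told apart. After centring the arrays that split called 0 genes, the real split 0 and the highest other 13, in fits whose prior also differed.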

How the results depend on the processing

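Centring of the arrays, the fits with the spread held or reweighted, the glucocorticoid list without Mt1 and Mt2 and the lists for the allele slope were chosen after seeing the data. Where a change is given, the cause was not tested, except as said for the spread. No paired analysis by replicate number was possible because each group had 1 array. Counts are given in the order lead, Mt-KO, heterozygous and allele slope, and were 13, 47, 13 and 412. They were 0, 0, 0 and 0 with GC-RMA, 0, 6, 0 and 92 without the brightness filter, 4, 20, 6 and 99 in the upper 40% of genes, and 0, 10, 0 and 508 with the mean over probe sets. They were 0, 4, 0 and 79 without the trend, 0, 1, 0 and 1 after quantile normalization and 0, 7, 0 and 20 after centring. With the spread of the deposited values held they were 15, 51, 13 and 205 after quantile normalization and 13, 47, 13 and 277 after centring, and with each gene's own spread weighted on the deposited values they were 0, 0, 0 and 0. The spread thus accounts for the loss of the lead, Mt-KO and heterozygous calls at these steps, and scaling also moves the allele slope, with 232 rising and 45 falling after centring. PLIER gave 13, 68, 10 and 142, and a threshold of 0.10 gave 16, 63, 13 and 737. Without the genotype block lead had 0 genes, and with a linear allele term Mt-KO had 7. Leaving out 1 genotype pair gave 1 to 2632 genes for lead, the highest without wild-type (2461 higher, 171 lower). Leaving out 1 array gave 8 to 4380 genes for Mt-KO and 3 to 2627 for the heterozygote. Without wild-type saline Mt-KO had 2429 and without wild-type lead 4380, with 2203 and 414 higher, and the lone wild-type array was assumed to vary like the others.

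Genes shifted at least 1.5-fold in all 3 genotypes numbered 0, against 11 with GC-RMA, 2 with PLIER, 10 at the lower fold limit and 2 to 4 when only 2 pairs were asked for. Lists called numbered 7 for lead and 7 for Mt-KO. With an estimated correlation and with fry they were 0 and 0. For lead they were 4 to 7 with 1 pair left out, and for Mt-KO 4 in the upper 40% of genes and 4 with the mean over probe sets. Without the wild-type pair cell division (0.326) and microglia (0.199) were not called for lead. Pericytes were not called with GC-RMA (0.930), PLIER (0.0672), the upper 40% of genes (0.207), no filter (0.0530) or without the heterozygous (0.503) or Mt-KO pair (0.630). Muscle, bone and skin were not called with GC-RMA (0.647), PLIER (0.756), quantile normalization (0.436), centring (0.248), no filter (0.635), no trend (0.0853), no block (0.0714) or without the heterozygous (0.422) or Mt-KO pair (0.152), and had too few genes in the upper 40%. For Mt-KO, PLIER did not call cerebellum (0.271) or cholesterol (0.685), GC-RMA did not call calcium (0.0562) or respiratory chain genes (0.334), quantile normalization did not call calcium (0.0527) or presynaptic genes (0.541), and without the filter cerebellum was not called (0.0627). In the upper 40% cerebellum (0.0518), presynaptic and respiratory chain genes (0.0745 for both) were not called, nor were cholesterol (0.0776), presynaptic (0.152) and calcium genes (0.0620) over mean probe sets. The respiratory chain list in Mt-KO turned after quantile normalization (limma adjusted p = 0.731), and the myelin list for lead turned without the wild-type pair (adjusted p from 3.2e-08 to 0.821 over the pairs left out), and was not called without the Mt-KO pair (0.122).

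Correlations of lead responses, for wild-type with heterozygous, wild-type with Mt-KO and heterozygous with Mt-KO, were -0.0996, -0.0898 and 0.287 with GC-RMA, -0.343, -0.289 and 0.438 with PLIER, and -0.388, -0.434 and 0.519 without the brightness filter. They were -0.259 and -0.213 for the wild-type pairs in the upper 40%, and -0.269 and 0.464 for heterozygous with wild-type and with Mt-KO over mean probe sets. Their signs were the same throughout.

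Mt1 in Mt-KO was -2.31 with GC-RMA (not passing), -0.83 over mean probe sets (passing) and -1.66 to -1.42 with 1 array left out, not passing without either Mt-KO array. Mt2 in Mt-KO did not pass with GC-RMA (-1.36), PLIER (-1.003), quantile normalization (-0.74), or, at -0.81, without the filter, over mean probe sets, without the trend and with the linear term, and was -0.93 to -0.70 with 1 array left out, passing in the 2 fits without a wild-type array and in none of the other 4. With 1 array left out the heterozygous difference was -0.74 to -0.41 for Mt1 and -0.59 to -0.41 for Mt2, passing without either wild-type array, and the lead coefficient of Mt1 was 0.083 to 0.28, passing without the wild-type pair. Signs turned for Mt3 with lead without the wild-type pair (-0.203 to 0.14 over the pairs left out), for Mt3 in the heterozygote without wild-type saline (0.19) or heterozygous saline (0.059; -0.45 to 0.19 over the arrays left out), for Eif2s3y in Mt-KO without wild-type saline (0.61) or Mt-KO saline (1.41; -3.64 to 1.41), and for Gh in the heterozygote without heterozygous lead (-0.15 to 1.80).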

Other observations

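The test of neighbours on the chromosome of Mt1 was chosen after the result was seen, and those on Hox and further pituitary genes before it.

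Hox genes, which mark hindbrain and cord, were lower with lead in 2 pairs, relative to the median gene tested. Apart from Hoxa5, 32 Hox genes were measured, 7 of them bright enough to be tested. Relative to the median gene, 29 of 32 were below 0 in the heterozygous pair (median -0.18) and 31 of 32 in the Mt-KO pair (median -0.19). In the wild-type pair 0 of 32 were (median 0.28). The median gene is that of the brighter genes tested, at -0.18, 0.15 and 0.09 in the wild-type, heterozygous and Mt-KO pairs. Subtracting these values moved all 32 genes in the directions given, so much of these counts and medians comes from the centring. As a hypothesis, the heterozygous and Mt-KO lead pools may hold less caudal brainstem and cord: the higher of their percentiles among random lists matched on level was 2.11, and after quantile normalization the percentiles were 1.36 and 0.02. The shifts themselves shrank at that step, to medians of 0.08, -0.07 and -0.13 in the wild-type, heterozygous and Mt-KO pairs, with 8, 22 and 23 of 32 below 0. Against it, the 4 group 13 genes shifted alike on the same centred values (medians -0.21 and -0.18). They mark the far posterior body rather than the brainstem, and most of the 32 are dim.

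Gh, Pomc and Cga were high in the heterozygous lead pool, whereas Prl was not (8.24 against 8.27 in heterozygous saline). As a hypothesis, pituitary tissue may have been included in that pool. The 3 further pituitary genes bright enough to test, Chga (0.07), Scg2 (0.14) and Lhx4 (-0.32), had a median at percentile 67.1, and 3 genes that the brain also expresses are too few to decide.

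Genes called as different between Mt-KO and wild-type were more often on the chromosome of Mt1, by a difference that rests on 6 calls. With the metallothioneins left out, 6 of 573 tested genes there were called (1.05%) against 39 of 10322 elsewhere (0.378%), an odds ratio of 2.79 (95% interval 0.961 to 6.67, two-sided Fisher's exact p = 0.0293). The interval takes in no difference although Fisher's exact p is under 0.05, and the test takes genes rather than pools as units. A strain segment carried around the targeted locus may contribute, but only Gadd45gip1 (-0.65) of the 6 lies within 10 Mb of Mt1. Exoc8 (0.99), Plvap (0.86), Ssbp4 (0.73), Gipc1 (0.72) and Terf2ip (0.59) lie farther away, and the 89 tested genes within 10 Mb had a median shift of 0.00.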
